A study of Mus musculus with 5 samples.

How the data were processed

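Adult mouse retina was dissociated with papain, cleaned over an albumin cushion and processed with the 10x Genomics 3′ kit, per the labels. The deposited files were UMI counts per gene and cell, made by the authors with Cell Ranger 3.0.2 against mm10 per the submitters' processing notes, with no scaling per gene or cell. A merged matrix held 31053 genes and 22559 cells of 2 WT and 2 Vsx2SE deletion libraries, and a WT matrix held the same 10906 WT cells. The suffix of each cell barcode gave its library. Suffixes 1 and 2 were WT, since all their barcodes were in the WT matrix, and suffixes 3 and 4 were the deletion libraries. WT cells held 3.24% fewer counts in the merged matrix (median ratio per cell 0.968, SD 0.00711, and 0.968 as the ratio of sums), while 148377 entries were higher there. How the matrices came to differ is not known. All values below come from the merged matrix. The labels give no batch or date, so handling and genotype could not be separated. The chromatin accessibility library (Cell Ranger ATAC 1.0.1 per the submitters' processing notes) was not analysed here.

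Cells with at least 200 detected genes and at most 30% mitochondrial counts were kept, 4458, 6245, 4940 and 6609 in libraries 1 to 4. The mitochondrial maximum was raised from 20% after 20% was seen to remove WT cells with bipolar markers. Scrublet, run per library with an expected rate of 0.8% per 1000 cells, called 3 of 22559 cells at its automatic threshold, so doublets were in effect not removed, and an alternative removed the 1015 cells with the highest scores. Counts were scaled to 10000 per cell and log-transformed in scanpy 1.11.5. Clusters came from 2000 variable genes without Vsx2 and its listed neighbours, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (igraph 0.11.9), which gave 23 clusters. Clusters were named "-like" from marker lists, and clusters led by markers of another class stayed unnamed. The lists were chosen before the data were examined, as were the tests, the rule for named genes and most alternatives, but the scoring that turned markers into names was written after the clusters were seen. WT bipolar-like cells were clustered again (1000 genes, 15 components, resolution 0.5), and a margin of 0.2 for naming sub-clusters was dropped after it left the rod bipolar-like sub-cluster unnamed.

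Shares of cells carry exact Clopper-Pearson 95% intervals, and a count of 0 allows up to 3 counts. Shares were compared with exact permutation of libraries and with an edgeR quasi-likelihood test on cell counts, Benjamini-Hochberg adjusted over classes. For genes, counts were summed per library over all kept cells or over the cells of a class, when each library had at least 30 such cells. Amacrine-like and bipolar-like sums did not reach this. Sums were tested with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood F test) with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F. Gene lists were tested on voom values with camera (limma 3.58.1, correlation preset to 0.01) and with fry, adjusted over lists. The change in fold between classes was tested with an interaction term. With 2 libraries against 2, the smallest exact permutation p is 0.333. The gene test was tested on simulated data with the real means and depths and a fixed dispersion of 0.01, not estimated from these data. It recovered 82.0%, 81.0%, 48.0% and 44.0% of 2-fold changes in whole-retina, rod-like, cone-like and Müller-glia-like sums, and called 0.107%, 0.0596%, 0.120% and 0.0709% of unchanged genes.

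CPM is a share of all counts, so a change in cell make-up moves every gene of a whole-retina sum. Genes were named as the 2 to 4 members of a list with the lowest adjusted p, and as the 12 (whole retina) or 8 (class) genes per direction with the lowest adjusted p among those with an absolute log2 fold change of at least 1 and no overlap between groups. Vsx2 and Otx2 were always named, and genes with Gm or Rik names were not. The pools held 650 lower and 41 higher genes in the whole retina, 20 and 22 in rod-like cells, and 6 and 8 in cone-like cells. Shares of cells with a UMI were also taken after thinning cells to 1000 UMIs. Alternatives were DESeq2 1.42.0, scaling by library size, no gene filter or at least 50 counts, no cell filter, other resolutions (0.5 and 2) and denominators, and leaving out each library. Added after the data were seen were a mitochondrial maximum of 20%, removal of the highest Scrublet scores, sums without bipolar-like cells, sums without single clusters and the share among cells that were not bipolar-like. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3.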

Results

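Single-cell 3′ RNA sequencing was carried out on dissociated adult mouse retina with droplet capture and molecular identifiers (UMIs), which count each captured transcript once. The series compared 2 wild-type (WT) libraries with 2 libraries from mice homozygous for a deletion named Vsx2SE, on a C57BL/6 background. From what is known of the study, Vsx2SE is a super-enhancer of Vsx2, a homeodomain transcription factor of retinal progenitors, bipolar neurons and some Müller glia. The coordinates of the deleted segment are not in the labels. The merged count matrix held 4584 and 6322 cells from the WT libraries and 4977 and 6676 cells from the deletion libraries. Total UMIs were 8547578 and 12332268 for WT libraries 1 and 2, and 7336615 and 11138257 for deletion libraries 3 and 4. The median cell held 1396.5, 1484.5, 1267 and 1380 UMIs in libraries 1 to 4. After filtering, 10703 WT and 11549 deletion cells were kept. Library numbers are those of the merged matrix, and the barcodes do not tie them to the replicate numbers of the labels. The labels do not say whether the libraries of a group came from separate animals, so each p-value measures the spread between these libraries. A single-cell chromatin accessibility library of WT retina belongs to the same series and was not analysed here.

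The Vsx2 transcript was examined first, as a check of the labels and as the direct readout of the deletion. Over all kept cells, Vsx2 (ENSMUSG00000021239, chromosome 12, 84569828 to 84595457 on GRCm38.p6) fell from 64.1 ± 5.26 CPM (counts scaled to a common library total) in WT to 8.84 ± 0.12 CPM in the deletion libraries (SD, n = 2 each). The individual libraries held 67.9 and 60.4 CPM in WT against 8.92 and 8.75 CPM after deletion, a log2 fold change of −2.79 ± 0.12 (SE, adjusted p = 0.000546). Bipolar-like cells of the WT libraries carried 441 CPM of Vsx2. Of the 162 Vsx2 counts left in the deletion libraries, 156 lay in Müller-glia-like cells and 6 in rod-like cells. Summed without bipolar-like cells, the whole-retina Vsx2 difference was 0.29 in log2 (adjusted p = 0.432), on the other side of 0. The count is of the 3′ end of the gene and not of the deleted segment, so it checks the labels only through the level of the transcript.

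Within Müller-glia-like cells, Vsx2 stood at 172 and 191 CPM in the WT libraries and at 255 and 264 CPM in the deletion libraries. The log2 difference of 0.50 ± 0.21 (SE, n = 2 each) did not pass the threshold (adjusted p = 0.762), on 88 and 156 counts. After thinning each cell to 1000 UMIs, Vsx2 was detected in 14.1% of 142 WT cells (95% exact interval 8.82 to 20.9) and 23.7% of 152 deletion cells (17.2 to 31.3). Without thinning these shares were 33.7% and 37.8%, at median depths of 2321 and 2172 UMIs. By library the unthinned shares were 38.6% and 30.5% in WT and 30.1% and 44.0% after deletion, so the groups overlapped. Rod-like cells, which should lack Vsx2 and served as the free-RNA background, showed it after thinning in 0.13% of WT cells and in 0 of 7801 deletion cells, at median depths of 1371 and 1308 UMIs. A count of 0 allows a share of cells with a UMI of up to 0.0385% there. Intervals cover counting error only.

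**Figure D1:**
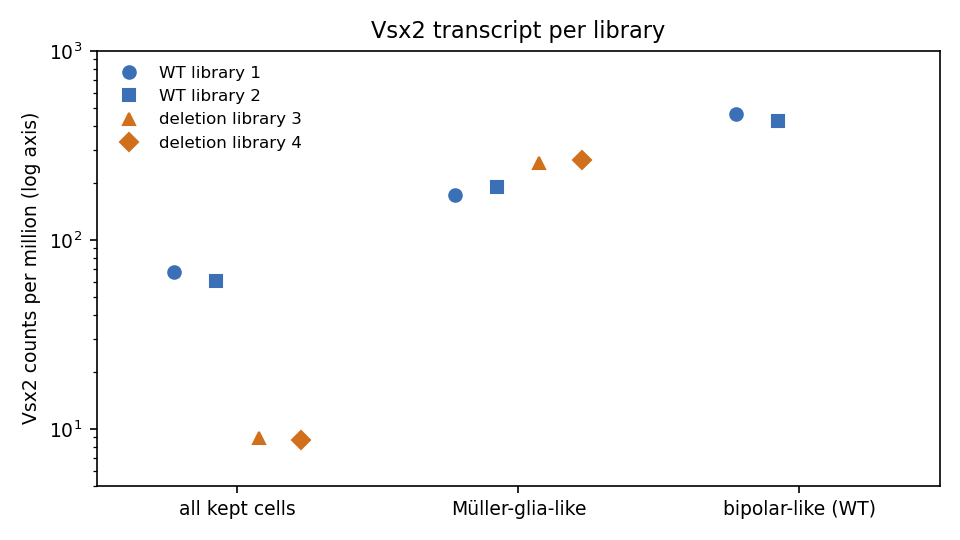
Vsx2 CPM (vertical log axis) in each library for all kept cells, Müller-glia-like cells and WT bipolar-like cells, with 1 point per library and no error bars. The deletion libraries lie at 8.92 and 8.75 CPM over all kept cells, below 60.4 and 67.9 CPM in WT, while in Müller-glia-like cells they lie at 255 and 264 CPM against 172 and 191 CPM.

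The next comparison concerned which cell classes each genotype held. Bipolar-like cells, the interneurons that carry photoreceptor output to the inner retina, made up 6.13% ± 0.68 of WT cells and 0.0101% ± 0.0143 of deletion cells (SD, n = 2 each). WT libraries 1 and 2 held 6.62% (95% exact interval 5.91 to 7.39) and 5.65% (5.09 to 6.25). Deletion library 3 held 0.0202% and library 4 held 0 of 6609 cells, which allows a share of up to 0.0454%. In numbers, 648 bipolar-like cells were found in WT and 1 in the deletion libraries, and that cell had 522 UMIs and no detected bipolar marker. An edgeR quasi-likelihood test on cell counts gave a log2 fold change of −9.13 (adjusted p = 0.00238 over 11 classes), while the exact two-sided permutation test of 2 against 2 libraries gave p = 0.333, the smallest it allows. A marker call without clusters, at 1000 UMIs per cell and at least 3 bipolar markers, gave 7.39% and 6.14% in WT against 0.0290% and 0.0392% after deletion. No cluster was confined to the deletion libraries: their highest share of a cluster was 65.9%, in the RPE-like cluster, beside 51.9% of all kept cells.

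Rod-like cells made up 84.8% ± 1.09 of WT and 92.4% ± 0.67 of deletion cells, a difference that did not pass (SD, n = 2 each; edgeR adjusted p = 0.319). Amacrine-like cells, inhibitory interneurons named from Gad1, Slc6a9, C1ql1 and related markers, were 2.56% and 2.61% of WT cells but 0.547% and 1.45% of deletion cells (adjusted p = 0.158). The size of the amacrine-like class depended on the clustering. At Leiden resolution 0.5 it averaged 4.25% of WT and 1.78% of deletion cells (edgeR adjusted p = 0.108). Cone-like cells were 2.39% ± 0.34 of WT and 3.26% ± 0.11 of deletion cells (adjusted p = 0.158). Müller-glia-like cells were 1.63% ± 0.08 and 1.82% ± 0.09 (adjusted p = 0.354), but 1.03% and 1.04% with no cell filter. In that setting a cluster of 188 cells led by Spc25, Glul and Fxyd1 was left unnamed (0.777% of WT and 0.892% of deletion cells). Among cells that were not bipolar-like, the rod-like share averaged 90.4% in WT and 92.4% after deletion, and amacrine-like shares were 2.74% and 2.77% against 0.547% and 1.45%. Among cells that were not rod-like, the amacrine-like share averaged 17.1% in WT (SD 1.47). Deletion libraries 3 and 4 held 7.65% and 17.9%, so only deletion library 3 lay lower on this denominator. Bipolar-like cells were 40.4% of that denominator in WT and 0.142% after deletion, which by itself raises the share of every other class. The 17.9% of deletion library 4 therefore does not show an unchanged amacrine-like class. With that denominator, which includes the bipolar-like cells, the shares that passed besides bipolar-like were cone-like (15.7% to 43.0%, edgeR adjusted p = 0.00397), Müller-glia-like (10.8% to 24.0%, 0.0161) and RPE-like (0.907% to 3.38%, 0.0161). The amacrine-like share passed the test when deletion library 3 was left out (adjusted p = 0.00529) or deletion library 4 (2.4e-05), and so did the rod-like and cone-like shares. None of these 3 shares passed without WT library 1 or WT library 2 (amacrine-like adjusted p = 0.321 and 0.430). Deletion library 3 held 27 amacrine-like cells, under the preset minimum of 30, so no gene test was made in that class.

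**Figure D2:**
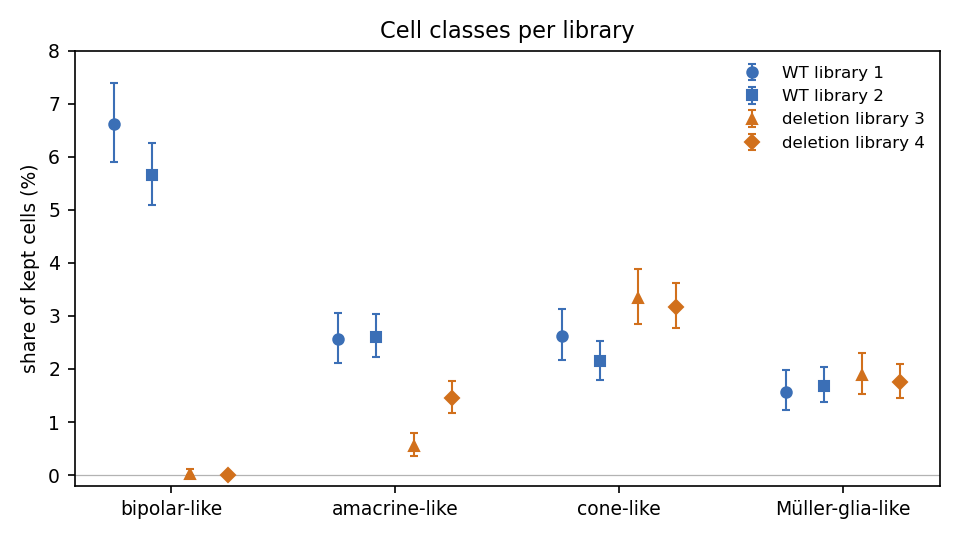
Share of kept cells (%, vertical axis) for 4 cell classes, with 1 point per library and bars for the 95% exact binomial interval. Bipolar-like cells are at 6.62% and 5.65% in the WT libraries and at 0.0202% and 0% in the deletion libraries, while Müller-glia-like shares are 1.57% and 1.68% against 1.88% and 1.76%, with overlapping intervals.

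The WT bipolar-like population was also divided into sub-types, since the deletion libraries held no counterpart to compare. Rod bipolar-like cells, led by Pcp2, Sebox and Trpm1 in their parent cluster, formed 34.7% ± 3.73 of WT bipolar-like cells (SD, n = 2; 223 cells). ON cone bipolar-like sub-clusters formed 41.8% ± 1.36 (270 cells) and OFF cone bipolar-like cells 10.5% ± 2.82 (69 cells). The remaining 86 cells stayed unnamed. Of these, 45 formed a sub-cluster led by cone genes such as Opn1sw, Pde6h and Arr3. The other 41 held Grik1 at 1317 CPM, beside 463 CPM in the OFF cone bipolar-like sub-cluster, and Grm6 at 15.3 CPM. The OFF cone bipolar-like share may therefore be too low. Vsx2 was detected in 71.5% of WT bipolar-like cells, Trpm1 in 77.9% and Grm6 in 67.9%, at a median depth of 4058.5 UMIs, beside 0.209%, 0.286% and 0.0770% of WT rod-like cells.

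Across the whole retina, genes of bipolar neurons fell further than any other group tested. Grm6, the glutamate receptor of ON bipolar cells, went from 64.6 CPM (1305 counts) to 0 counts, at least 387-fold lower, taking 3 counts over the deletion group as the floor. Trpm1, the cation channel of the same cells, fell from 204 ± 37.1 to 0.75 ± 0.47 CPM, and Pcp2 from 828 ± 119 CPM to 1 count. Isl1, a transcription factor, fell from 93.9 ± 19.2 to 0.0902 ± 0.13 CPM (SD, n = 2 each). In all, 1613 of 13261 genes changed (edgeR, adjusted p under 0.05), 662 upward and 951 downward. Leaving out WT library 1 or 2 left 52 or 42 changed genes, and sums without bipolar-like cells left 6. Without bipolar-like cells, 2790 of 12942 genes still had an unadjusted p under 0.05 (edgeR), so the 6 calls do not show that little else changed. Bipolar-like cells held 13.3% and 12.7% of the kept counts of WT libraries 1 and 2.

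Of the 15 bipolar markers, 14 fell and Prkca did not pass, with −0.61 ± 0.16 (SE) in log2. All 15 passed when adjusted over the list alone. The list's camera test gave an adjusted p of 4.2e-16, and adjusted p = 0.430 with an estimated correlation between genes. With 4 libraries to estimate it from, no whole-retina list passed in that setting, so it says little about any 1 list. The strongest calls besides those above were Cabp5, a calcium-binding protein, with −3.99 ± 0.10, Gng13, a G protein subunit, with −6.41 ± 0.24, and Scgn, encoding secretagogin, which went from 813 counts to 2. Of the 15 bipolar transcription factors 12 fell, the same number when adjusted over the list alone (camera adjusted p = 2.8e-09, and 0.430 as adjusted p with an estimated correlation). Among them were Sebox (−2.96 ± 0.12) and Vsx1, which went from 329 counts to 0, at least 97.6-fold lower. Otx2, which photoreceptors also express, stood at 147 ± 6.15 and 152 ± 6.77 CPM (0.12 ± 0.08, adjusted p = 0.373). In the mGluR6 cascade, which carries the light response of ON bipolar cells, 8 of 13 genes fell and 2 rose, and 12 passed when adjusted over the list alone. Gpr179 (−3.89 ± 0.28) and Rgs11 (−3.06 ± 0.25) were among those that fell, and Gnb5 rose (0.37 ± 0.08). The cascade's camera test gave adjusted p = 5.7e-05, and 0.430 as adjusted p with an estimated correlation. Among OFF cone bipolar genes 6 of 11 fell, including Grik1 (−4.82 ± 0.28) and Fezf2 (74 counts to 1), and 10 of 11 passed when adjusted over the list alone. Of the rod bipolar genes 6 of 7 fell, and all 7 passed when adjusted over the list alone. The camera test gave adjusted p of 5.1e-06 and 5.2e-08 for these lists, and 0.430 as adjusted p with an estimated correlation for each.

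The rule for named genes added others without a list, all lower in both deletion libraries than in both WT libraries. These were Trnp1 (−5.41 ± 0.18, 347 to 7.60 CPM), Gsg1 (1481 counts to 3), Gabrr1, a GABA receptor subunit (−5.88 ± 0.21), and Lrtm1 (−2.81 ± 0.12). Of the 92 Cabp5 counts left after deletion, 88 lay in cone-like cells. Of the 164 Sebox counts left, 122 lay in rod-like and 40 in cone-like cells. With bipolar-like cells left out of the sums, the fold changes of Cabp5, Sebox and Gpr179 turned to 0.19, 0.27 and 0.38 without passing.

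Lists of photoreceptor and Müller genes were tested in the same whole-retina sums. Of 18 rod phototransduction genes 11 rose, among them Rcvrn, encoding recoverin (0.54 ± 0.09), and Gnat1, the rod transducin (0.53 ± 0.09), and all 18 passed when adjusted over the list alone. The camera test gave adjusted p = 8.3e-10, and 0.515 as adjusted p with an estimated correlation. Of 13 photoreceptor transcription factors 7 rose, including Nrl (0.48 ± 0.07), Neurod1 (0.63 ± 0.07) and Samd7 (0.88 ± 0.14), and 10 passed when adjusted over the list alone. Their camera test gave adjusted p = 1.0e-06, and 0.430 as adjusted p with an estimated correlation. Of 9 cone markers, 2 rose, Arr3 (0.42 ± 0.10) and Gngt2 (0.59 ± 0.14), and of 12 Müller markers, 3 rose, with Glul at 0.52 ± 0.12 and Aqp4 at 0.52 ± 0.09. Adjusted over each list alone, 5 and 4 passed. Their camera tests gave adjusted p of 0.00498 and 0.00403, and 0.547 and 0.535 as adjusted p with an estimated correlation. Beside these groups, the rod-like share was 84.8% in WT and 92.4% after deletion, and 0 of 18 rod phototransduction genes passed within rod-like cells.

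Lists of inner retinal interneurons were tested next. Of 7 genes listed for AII amacrine cells, which relay rod signals, 6 fell, among them Prox1 (−2.10 ± 0.15), Nfia (−1.15 ± 0.17), Slc6a9, a glycine transporter (−1.23 ± 0.19), and Gjd2, the gap junction protein connexin 36 (−0.42 ± 0.08), and the same number passed when adjusted over the list alone. Several of these are not specific to amacrine cells. Without bipolar-like cells, where only 6 of 12942 genes passed, the log2 fold changes were −0.59 for Prox1, −0.45 for Nfia and −0.16 for Gjd2, but −1.41 for Slc6a9, and none of the 4 passed. Of 15 GABA and glycine amacrine genes 2 fell, Slc6a9 and Tcf4 (−0.76 ± 0.18), and 8 passed when adjusted over the list alone. The camera tests gave adjusted p of 6.0e-05 and 5.7e-05, and 0.430 and 0.547 as adjusted p with an estimated correlation. Of 16 ribbon synapse genes 6 rose, such as Lrit2 (0.62 ± 0.08) and Cplx4 (0.54 ± 0.08), while 2 fell, including Cplx3 (−1.21 ± 0.15), and 9 passed when adjusted over the list alone. That list's camera test gave adjusted p = 0.0448, and 0.547 as adjusted p with an estimated correlation. Amacrine-like cells were 2.56% and 2.61% of the WT libraries and 0.547% and 1.45% of the deletion libraries.

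Among the genes that rose at least 1 log2 unit with both deletion libraries above both WT libraries, Abhd14b (ENSMUSG00000042073), an alpha/beta hydrolase, and Tcea3 (ENSMUSG00000001604), a transcription elongation factor, had the lowest p-values. Abhd14b rose from 29.4 ± 1.39 to 106 ± 0.0027 CPM (1.92 ± 0.08 SE in log2) and Tcea3 from 13.1 ± 0.22 to 65.9 ± 6.10 CPM (2.40 ± 0.12). The histone gene Hist3h2a rose from 270 to 524 CPM, the chaperone Hspa1b from 34.2 to 72.0 CPM and the fatty acid-binding protein Fabp7 from 6.53 to 16.9 CPM. Dct, an enzyme of melanin synthesis (2.64 ± 0.27), and Slc16a8, a lactate transporter of the pigment epithelium (1.70 ± 0.26), rose beside RPE-like shares of 0.136% ± 0.0339 in WT and 0.255% ± 0.0399 after deletion. Glb1l3, Apela, Tshz2 and Asap3 rose by 1.17, 1.17, 1.20 and 2.32 in log2, and Wdfy1 from 11.5 to 31.6 CPM. Abhd14b (chromosome 9, 106447737 to 106452923) overlaps Abhd14a (106440051 to 106451203), and reads of 1 gene could be counted for the other, so both values are uncertain. Asap3 (chromosome 4, 136206350 to 136246577) and Tcea3 (136247936 to 136274903) are neighbours. Abhd14b, Tcea3, Hist3h2a and Pcp2 were among the 6 genes that still passed without bipolar-like cells. With scaling by library size alone the whole-retina calls split into 362 higher and 921 lower, with the median gene shifted by −0.07 in log2.

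Rod-like cells were compared next, to ask what the deletion changed in the photoreceptors themselves. Abhd14b rose from 13.5 ± 0.97 to 105 ± 1.77 CPM (2.95 ± 0.10 SE in log2, n = 2 each), Tcea3 from 14.9 to 70.6 CPM (2.22 ± 0.10) and Hist3h2a from 207 to 531 CPM (1.33 ± 0.08). Rab6b, a small GTPase of membrane traffic, fell from 64.4 ± 18.2 to 7.56 ± 3.90 CPM (−3.05 ± 0.23). No rod phototransduction gene was called: 0 of 18 rod phototransduction genes passed the edgeR test, also when adjusted over the list alone, with Rho at −0.10 ± 0.10 and Gnat1 at 0.08 ± 0.10. In all, 176 of 10260 genes changed, 107 upward and 69 downward.

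Of 9 heat shock genes, which encode protein chaperones, 5 rose in rod-like cells and all 9 passed when adjusted over the list alone. Hspa8 rose from 458 to 896 CPM (0.94 ± 0.08), Hsp90ab1 from 170 to 325 CPM (0.91 ± 0.08), and Hspa1b and Hspa1a by 0.72 ± 0.09 and 0.41 ± 0.08. The last 2 are near-identical copies and their separate values are uncertain. The camera test gave adjusted p = 4.3e-14, and 0.548 as adjusted p with an estimated correlation, while fry, which asks whether a list moves 1 way, gave 0.0401. Of 12 photoreceptor transcription factors 1 rose, Samd7 (0.45 ± 0.09), and 2 passed when adjusted over the list alone (camera adjusted p = 0.0413, and 0.548 as adjusted p with an estimated correlation). Otx2 stood at 0.12 ± 0.08 (adjusted p = 0.504). Of 13 mitochondrially encoded genes 3 fell, mt-Nd2 (−0.62 ± 0.09), mt-Cytb (−0.50 ± 0.09) and mt-Atp6 (−0.47 ± 0.10), and 8 passed when adjusted over the list alone, beside median mitochondrial shares over all cells of 8.93% and 8.18% in WT and 6.64% and 6.49% after deletion. The mitochondrial list's camera test gave adjusted p = 7.1e-05, and 0.842 as adjusted p with an estimated correlation. In cone-like cells 1 of these 13 genes rose and 0 fell, and 6 passed when adjusted over the list alone, 2 higher and 4 lower.

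Other genes that rose in rod-like cells were Scg2, a secretogranin (2.54 ± 0.20), Plppr4 (4.65 ± 0.47), Tshz2 (4 counts in WT and 200 after deletion), Asap3 (2.41 ± 0.27) and Igsf21 (2.11 ± 0.24). Among those that fell were Akr1e1, an aldo-keto reductase (−1.11 ± 0.11), Arhgap31 (−1.26 ± 0.17), Fabp4 (−1.11 ± 0.17) and Pcp4 (−2.17 ± 0.35). Of 5 bipolar markers tested in rod-like cells 3 fell, also when adjusted over the list alone. Pcp2 went from 132 counts to 1, Gng13 from 148 to 4, and Trpm1 from 27 counts to 0, at least 10.1-fold lower. In WT these reached 10.5, 12.3 and 2.04 CPM in rod-like cells, while Trpm1 reached 1524 CPM in WT bipolar-like cells. The bipolar list's camera test gave adjusted p = 2.9e-04, and 0.548 as adjusted p with an estimated correlation. The count of changed genes was 591 without WT library 1 and 63 without deletion library 4, 281 without a rod-like cluster that took 65.2% of its cells from WT library 2, and 106 with DESeq2.

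In cone-like cells, Abhd14b rose from 35.5 ± 1.44 to 178 ± 23.0 CPM (2.30 ± 0.21 SE in log2, n = 2 each). Hspa5, a chaperone of the endoplasmic reticulum, rose from 320 ± 78.4 to 797 ± 50.9 CPM (1.26 ± 0.12), and Sdc4, a cell surface proteoglycan, from 52.6 to 114 CPM (1.06 ± 0.21). Zc3h6, a zinc finger gene, fell from 77.5 ± 34.3 to 12.6 ± 1.53 CPM (−2.59 ± 0.36). Gnat2, the cone transducin, fell by 0.36 in log2 (SE 0.0748). In all, 61 of 6893 genes changed, 27 upward and 34 downward.

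Of 9 heat shock genes 4 rose in cone-like cells: Hspa8 (0.68 ± 0.09), Hsp90ab1 (0.81 ± 0.10), Hsp90aa1 (0.41 ± 0.08) and Hsph1 (1.02 ± 0.20), the same number as when adjusted over the list alone. The camera test gave adjusted p = 6.2e-12, and 0.322 as adjusted p with an estimated correlation. Gnat2 was the only 1 of 11 cone phototransduction genes to pass over all genes, and 5 passed when adjusted over the list alone, 4 of them lower. That list's camera test gave adjusted p = 1.9e-04, and 0.469 as adjusted p with an estimated correlation. Of 8 rod markers 1 rose (Gngt1) and 4 passed when adjusted over the list alone, all higher (camera adjusted p = 1.2e-05, and 0.469 as adjusted p with an estimated correlation). Of 9 cone markers 1 fell (Gnat2) and 5 passed when adjusted over the list alone, 4 of them lower (camera adjusted p = 3.7e-05, and 0.415 as adjusted p with an estimated correlation). Of 18 rod phototransduction genes, Sag (−0.47 ± 0.07) and Guca1b (−0.58 ± 0.14) fell and Gngt1 (0.30 ± 0.07) rose, and 6 passed when adjusted over the list alone (camera adjusted p = 0.601, and 0.823 as adjusted p with an estimated correlation). Otx2 stood at 0.28 ± 0.19 (adjusted p = 0.655). Other genes that rose were Ahsa2 (1.73 ± 0.33), Tagln3 (1.96 ± 0.47), Tcea3 (1.05 ± 0.23) and AC149090.1, a gene without an assigned symbol (1.68 ± 0.19). Akr1e1 (−1.74 ± 0.29), Ccdc24 (−1.45 ± 0.28), Med13l (−1.36 ± 0.28) and Abhd14a (−1.06 ± 0.25) fell, the last with the overlap given above. The count was 113 without WT library 1, 21 with DESeq2 and 99 with a minimum of 50 counts, and library-size scaling split the calls into 53 higher and 37 lower.

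**Figure D3:**
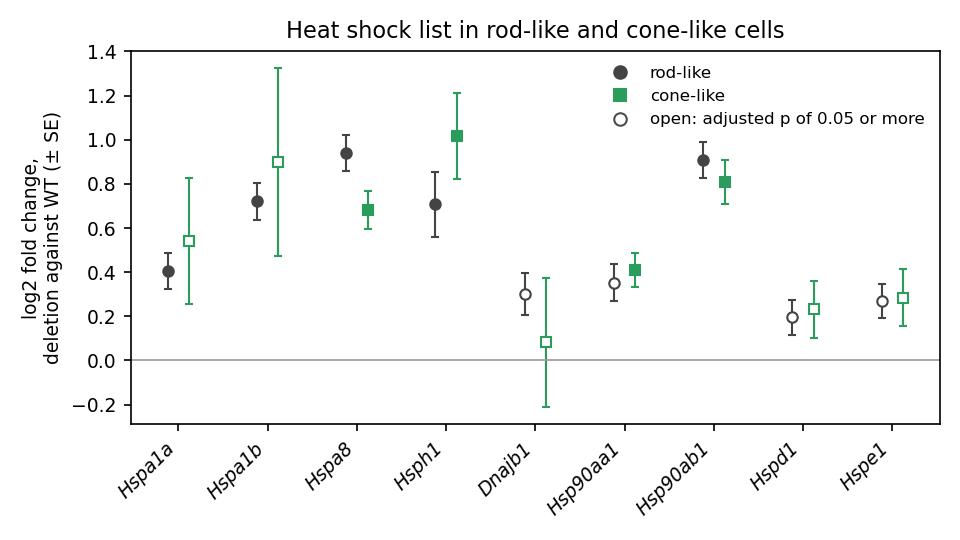
Log2 fold change of deletion against WT (vertical axis, ± SE, 2 libraries per group) for the 9 heat shock genes tested in rod-like cells (circles) and in cone-like cells (squares), with open symbols for an adjusted p of 0.05 or more. Hspa8 lies at 0.94 and 0.68 and Hsp90ab1 at 0.91 and 0.81 in rod-like and cone-like cells.

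Among 6696 genes tested in both photoreceptor classes, 15 rose in both and 8 fell in both, against 0.351 and 0.241 for independent lists of these sizes. Abhd14b, Tcea3, Hspa8 and Hspa5 were among the first, and Zc3h6, Akr1e1 and Abhd14a among the second. Both classes came from the same 4 libraries, so part of the overlap may lie in what a library shares across its cells.

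In Müller-glia-like cells, the support glia of the retina, 0 of 4429 genes passed with edgeR or with DESeq2, and 282 had an unadjusted p under 0.05. Rlbp1, a retinoid-binding protein on the homeostasis list, stood at −0.36 ± 0.20, and Apoe, a Müller marker outside that list, at −0.39 ± 0.19. Among 9 reactive gliosis genes Gfap stood at 0.32 ± 0.30 and Fgf2 at 1.56 ± 0.53 (SE, n = 2 each). Of 12 homeostasis genes and of 9 gliosis genes, 0 passed, also when adjusted over each list alone. The homeostasis list had a camera test adjusted p of 0.0430 downward, and 0.518 as adjusted p with an estimated correlation. The gliosis list had a camera adjusted p of 0.350, and 0.601 as adjusted p with an estimated correlation. Of 8 rod markers 0 passed and 3 did when adjusted over the list alone, with a median of 0.65 in log2 (camera test adjusted p = 1.1e-04, and 0.518 as adjusted p with an estimated correlation), beside a Müller-glia-like cluster rich in rod RNA that held 65 WT and 89 deletion cells. That cluster was led by Ctgf, Gfap and S100b, at a median of 912.5 UMIs, and Gfap and S100b are also on the astrocyte marker list. Whether its share of cells moved the Gfap value was not tested. Simulated 2-fold changes were recovered for 44.0% of genes at this depth and the fixed dispersion used, and 4-fold changes for 82.0%. Leaving out any 1 library gave 33 to 40 changed genes, and leaving out the rod-RNA-rich cluster gave 3.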

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

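Tests of neighbouring genes, of distance to Vsx2 and of free rod RNA for the genes shared by rod-like and cone-like cells, the immediate early test, the separate look at 20 of the bipolar-specific genes in the deletion rods and the interval around the share of genes outside the Poisson range were chosen only after the results were seen. The change after deletion differed between cell classes for some genes, by an interaction test on the same 4 libraries (edgeR). It differed for 2 of 3877 genes between rod-like and Müller-glia-like cells, Tshz2 (−4.67 in log2, Müller-glia-like minus rod-like) and Abhd14b (−3.23), with 288 genes at an unadjusted p under 0.05. It differed for 36 of 6696 genes between rod-like and cone-like cells (517 unadjusted), among them Gng13 (5.97, cone-like minus rod-like), Hist3h2a (−1.07), Zc3h6 and mt-Nd2. It differed for 1 of 3639 genes between cone-like and Müller-glia-like cells, Abhd14b (−2.63), with 229 unadjusted.

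Bipolar transcripts fell in rod-like cells, which were not bipolar cells by their clusters. Free RNA from bipolar cells in the WT droplets may be the source. Of 6 bipolar markers tested in cone-like cells, 0 fell, and 3 were higher when adjusted over the list alone (median 0.61 in log2). The listed markers Cabp5 and Sebox were detected in 15.7% and 9.6% of cone-like cells of the deletion libraries. Markers present there without bipolar cells cannot show a loss of free bipolar RNA, so this comparison does not decide. In Müller-glia-like cells only 1 was tested (0.28). Over 91 bipolar-specific genes, counts in WT rod-like cells followed the level in bipolar-like cells (Spearman rho 0.589 across genes, which are not independent replicates, with p = 1e-05, the smallest the permutations can give). Of the 91 genes, 20 were taken for their 0 counts in deletion cone-like and Müller-glia-like cells. Their transcripts were 4.57 times as frequent per cell in Müller-glia-like as in rod-like WT cells (0.12 and 0.0263 UMIs per cell, at median depths of 2321 and 1371 UMIs). In WT cone-like cells they were 6.82 times as frequent as in rod-like cells (0.179 UMIs per cell, at a median depth of 4846 UMIs). These ratios cannot decide on transcription of these 20 genes by WT rods, or on their lower transcription in deletion rods. A higher level in other classes does not exclude a lower level made by rods. The excess over rod-like cells was also larger than the difference in depth, so free RNA in equal amounts per droplet would not give it. Only 1 of Pcp2, Gng13 and Trpm1 is among the 20, so the ratios do not cover the fall of all of them. The summed level of Pcp2, Gng13 and Trpm1 in WT rod-like cells did not fall on removing the highest Scrublet scores (23.4 to 23.9 CPM, a percent fall of −2.0). This cannot decide on doublets of rods and bipolar cells, since the highest scores were not shown to capture them. For the other 71 genes, too, lower transcription in rods of the deletion retina could not be told apart. Of them 16, and 20.9% of all 91, lay outside the range of 1 common ratio. The preset bound was 20%, and the interval for all 91 was 13.1 to 30.7.

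Of the genes changed in both rod-like and cone-like cells, 15 were higher and 8 lower. Free rod RNA in cone-like droplets is opposed by all 23 genes, which stood more than 2 times above the level it would give (lowest ratio 27.3, median 42.4). A segment around Vsx2 is opposed by 0 of 21 shared genes with a position within 10 Mb. Other chromosome segments that differ between the genotypes, such as strain variants, stay open. The 3 neighbouring pairs within 1 Mb all lay among Rpl29, Abhd14a, Abhd14b and Manf on chromosome 9, a group noticed before the test that includes the overlapping Abhd14a and Abhd14b, so their excess over random sets (mean 0.372 in 10000 sets, permutation p = 0.0053) restates what was seen. The other 17 genes held 0 such pairs. First versions of these tests gave a ratio of 48.8 for Abhd14b alone. They gave 1 called rod-like gene among 99 tested within 10 Mb of Vsx2 (random mean 1.59, permutation p = 0.805). They also gave 25 neighbouring pairs among all called rod-like genes (random mean 20.4, permutation p = 0.161). Some of these pairs rose together, such as Scg2 and Wdfy1 (chromosome 1), Agl and Plppr4 (chromosome 3) and Asap3 and Tcea3 (chromosome 4). Others moved in opposite directions, such as Glb1l2 and Glb1l3 (chromosome 9). These examples were picked after their values were seen, so a shared segment stays untested for them.

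Of 9 heat shock genes tested, 5 rose in rod-like and 4 in cone-like cells of the deletion libraries, and 9 and 4 passed when adjusted over the list alone. The camera tests gave adjusted p of 4.3e-14 and 6.2e-12, and 0.548 and 0.322 as adjusted p with an estimated correlation. Handling that reached all cells cannot be told apart from genotype, which the design confounds with it: the median log2 ratio was 0.115 in amacrine-like sums (6 of 9 genes higher) and 0.299 in Müller-glia-like sums (7 of 9). A different time of day also stays open, with clock gene medians of −0.327 in rod-like cells (6 of 6 lower) and −0.198 in cone-like cells (4 of 6 lower) and Dbp past the threshold in both. An immediate early response during dissociation stays open too: 0 of 13 such genes passed over all genes in rod-like cells (edgeR), but 1 passed when adjusted over the list alone, higher (Junb, 0.44 ± 0.12), and the list median was 0.0924 (camera adjusted p = 0.233, and 0.841 as adjusted p with an estimated correlation). An effect of the deletion on photoreceptors was not tested apart from these and stays open.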

How the results depend on the processing

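The alternatives added after the data were seen are the mitochondrial maximum of 20%, removal of the highest Scrublet scores, sums without bipolar-like cells or without single clusters, and the share among cells that were not bipolar-like. The bipolar-like share passed in every setting that tested it. No paired analysis was possible because the barcodes carry no replicate number, and amacrine-like and bipolar-like gene tests were not run for want of cells. Where 1 library is left in a group, it is assumed to vary like the other group. Unless stated, the cause was not tested.

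Whole-retina changed genes (1613) were 3436 with no gene filter, where more genes were tested, and 6 without bipolar-like cells, while leaving out single libraries gave 42 to 1952, with 39 and 52 calls in common with all libraries without WT libraries 2 and 1. Rod-like counts (176) were 106 with DESeq2, 528 with no gene filter, 281 without the cluster mostly of WT library 2, and 63 to 591 without single libraries. Cone-like counts (61) were 21 with DESeq2, 107 with no gene filter, 99 with at least 50 counts, where fewer genes were tested, and 58 to 113 without single libraries. Müller-glia-like counts (0) were 43 with no gene filter, 15 without the highest Scrublet scores, 3 without the rod-RNA-rich cluster, and 33 to 40 without single libraries. Classes passing the share test (1 of 11) were 2 with no cell filter, 2 without the highest Scrublet scores, 4 among cells that were not rod-like, 0 among cells that were not bipolar-like, where that class is absent, and 1 to 5 without single libraries. Gene lists passing with an estimated correlation were 0 of 37 in the whole retina and 0 of 39 in Müller-glia-like and rod-like cells, from 24 and 14. As the bipolar markers, of which 14 of 15 fell, also did not pass, this setting could hardly pass any list with 4 libraries. The ON cone bipolar-like share (41.8%) was 47.0% at sub-clustering resolution 1 and 38.7% with Scrublet calls kept, both counting as ON cone a sub-cluster (34 and 33 cells) led by rod genes such as Rho and Gnat1.

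Without bipolar-like cells the whole-retina log2 fold changes turned to 0.29 for Vsx2, 0.19 for Cabp5, 0.27 for Sebox and 0.38 for Gpr179, which the construction explains. Without single libraries Gnat1 in rod-like cells ran from −0.032 to 0.201 and Gfap in Müller-glia-like cells from −0.029 to 0.75, neither past the threshold with all libraries. Apart from leave-one-out settings, named genes kept direction and call in 449 whole-retina, 267 rod-like, 148 cone-like and 42 Müller-glia-like cases, and lost the call in 72, 2 and 7. On leaving out libraries they kept it in 157, 118, 83 and 17 cases and lost it in 110, 16 and 17. The Müller-glia-like share was 1.03% in WT and 1.04% after deletion with no cell filter, where a cluster led by Spc25, Glul and Fxyd1 was left unnamed. It was 1.02%, 0.977%, 0.990% and 1.05% in libraries 1 to 4 without the highest Scrublet scores. At a mitochondrial maximum of 20% it was 1.07% in WT and 1.06% after deletion. At the fixed dispersion used, simulated 2-fold changes were recovered for 44.0% of genes in Müller-glia-like and 48.0% in cone-like sums. This limits what a count of 0 can show, for that dispersion only.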

Other observations

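Further groups in the whole-retina sums were tested with edgeR and camera. Of 10 heat shock genes 6 rose, among them Hspa1a (0.82 ± 0.07), Hsph1 (0.83 ± 0.10) and Hsp90aa1 (0.59 ± 0.07), the same number when adjusted over the list alone (camera adjusted p = 1.4e-04, and 0.430 as adjusted p with an estimated correlation). Of 9 ganglion cell markers 3 fell, Pou4f1 (−3.80 ± 0.71), Sncg (−2.22 ± 0.38) and Rbpms (−1.39 ± 0.27), also over the list alone (4.6e-04 and 0.535). Of 4 RPE markers 2 rose, Ttr (1.51 ± 0.33) and Lrat (1.82 ± 0.42), also over the list alone (0.0219 and 0.535). Of 10 amacrine markers 1 fell, Slc6a9 (2.6e-04 and 0.547), and of 4 starburst genes 2 fell, Isl1 and Slitrk6 (0.286 and 0.746), both of which bipolar cells also express. Of 8 rod markers 6 rose and all 8 passed when adjusted over the list alone (3.5e-06 and 0.515). Of 11 cone phototransduction genes 2 rose and 6 passed over the list alone, 5 of them higher (0.0149 and 0.620). Of 14 Müller homeostasis genes 2 rose, Glul and Aqp4 (0.0112 and 0.535). Of the sub-type markers 4 of 5 fell for rod bipolar, 5 of 5 for ON cone bipolar and 4 of 7 for OFF cone bipolar cells (3.5e-06, 1.6e-06 and 4.3e-04, and 0.430 each with an estimated correlation).

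Of 15 immediate early genes Atf3 rose (0.72 ± 0.16) and Nr4a1 fell (−1.75 ± 0.31), with camera adjusted p = 0.998. Of 15 interferon genes Irf7 rose (0.87 ± 0.18) although the list median was −0.29 (0.632), and of 13 mitochondrially encoded genes mt-Nd2 fell (−0.41 ± 0.09, 0.0401, and 0.746 with an estimated correlation). Of 15 reactive gliosis genes Cp rose (0.77 ± 0.17), and 0 passed over the list alone (0.0448 and 0.515). Of 8 apoptosis genes 0 passed (0.159). Of 13 genes listed as neighbours of Vsx2, Bbof1 rose (0.59 ± 0.08) and Areg went from 29 counts to 0, at least 8.61-fold lower (0.997). Areg lies on chromosome 5 and was put on that list by mistake. Among the lists of cell types, S100b rose of 4 astrocyte markers (2.29 ± 0.54), Vtn rose of 6 pericyte markers (0.47 ± 0.09) although the list median was −1.11, and Esam fell of 8 endothelial markers (−1.77 ± 0.40). Of 4 horizontal cell, 10 microglia, 5 red blood cell, 4 progenitor, 4 crystallin, 1 fibroblast and 1 other immune genes tested, 0 passed, and no lens marker was tested. The red blood cell list had a median of 1.05 but a camera direction downward (0.998), and the microglia list a median of 0.10 but a mean of −0.01.

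Outside the rule for named genes, and chosen after their values were seen, Hspa5 (0.86 ± 0.08), Xbp1 (0.83 ± 0.09) and Manf (0.63 ± 0.08), genes of the endoplasmic reticulum stress response, rose in rod-like cells, and Manf rose in cone-like cells (0.90 ± 0.14). Rbm3, a cold-inducible RNA-binding protein, fell in rod-like (−0.91 ± 0.10) and cone-like cells (−0.78 ± 0.13). Cirbp, also cold-inducible, fell in cone-like cells (−0.57 ± 0.13, edgeR adjusted p = 0.0286) and did not pass in rod-like cells (−0.41 ± 0.09, 0.0532). Dbp, an output gene of the circadian clock, fell in rod-like and cone-like cells (−0.84 ± 0.13 and −0.68 ± 0.12). In Müller-glia-like cells S100b stood at 1.96 ± 0.40 (edgeR adjusted p = 0.328). S100b was among the leading genes of the Müller-glia-like cluster rich in rod RNA. Unnamed cluster 13, led by Nefl, Ebf1 and Calb2, held 1.19% and 1.14% of WT cells and 0.162% and 0.711% of deletion cells (edgeR adjusted p = 0.190). It passed without deletion library 4 (1.95e-04) but not without deletion library 3 (0.0551), WT library 1 (0.412) or WT library 2 (0.431). No cluster took the name of horizontal or ganglion cells.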
